A study of Mus musculus with 27 samples.

How the data were processed

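The series was measured in mouse hippocampus with 4 kinds of libraries, each in 3 replicates per group. Per the labels, Ythdf1-CLIP used UV crosslinked hippocampus, a rabbit antibody against Ythdf1, partial digestion with RNase T1 in 2 rounds, end repair with T4 PNK and the NEBNext small RNA kit, and m6A-CLIP used poly(A) RNA with a rabbit antibody against m6A and the same enzymes and kit. RNA-seq of hippocampus labelled WT or Ythdf1 KO used a TruSeq stranded mRNA kit after 1 round of poly(A) selection. The DG libraries used a full-length protocol, after 1 round of poly(A) selection for input and 2 rounds for m6A-RIP. Libraries were grouped by their labels into mock and ECT, input and RIP, and WT and KO. The inputs of the Ythdf1-CLIP were not used here, since only peak lists were analysed for CLIP.

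The submitters' processing notes name TopHat2 2.0.14, Cuffnorm, cutadapt, Bowtie2, Trimmomatic, STAR and DESeq2 and the genome build mm10, and do not say which step each served. The DG values are counts of reads per gene, deposited as whole numbers that the authors had not scaled, with a companion table of RPKM. The gene length implied by counts, library totals and deposited RPKM was the same in all libraries within 0.1% for 100% of 19281 genes checked, which showed the tables to hold the same libraries. Transcript lengths used below are these implied lengths. The hippocampal WT and KO values are RPKM as deposited by the authors, and the read counts behind them could not be recovered. The CLIP files are peak lists with a position, a gene name, a location class and a number of mutations per peak, which is the score the authors deposited, and a high-confidence list per assay. How peaks were called and how the high-confidence lists were chosen is not given in the sources used here. Gene symbols that a spreadsheet had turned into dates were restored for all but 5 of 27 in the count table and 4 of 26 in the RPKM table.

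Before the data were examined, the comparisons, tests, thresholds, alternatives, gene lists and the rule for naming genes were fixed. DG counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling and filterByExpr. ECT was compared with mock separately in input and in RIP, and a fit of all 12 libraries gave mock RIP over mock input and the change of that ratio with ECT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and for RIP over input also at an absolute log2 ratio of at least 1. CPM values in the text are TMM-scaled except those of choroid plexus genes in single libraries, which are counts over library totals. WT and KO were compared with limma 3.58.1 (trend and robust) on log2(RPKM + 1) for genes with a mean of at least 1 RPKM. Log2 ratios of RIP over input are relative to the typical gene, because scaling sets that gene to 0.

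Fixed lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. A list was called at adjusted p under 0.05 with the preset value. A member count adjusted over the list alone repeats the adjustment within the list. The list of ribosomal protein genes takes symbols beginning with Rpl or Rps followed by a digit, without pseudogenes, and leaves out kinase and binding protein genes that share the prefix, a restriction the first wording lacked. A list of mitochondrial transcripts had 0 members in the tables. The 2 sets of CLIP genes were tested with camera in the same way without adjustment. Peaks overlapped when they shared at least 1 bp on the same strand, and the same peaks shifted by 1000 bp along the genome served as the comparison. Gene sets were compared with Fisher's exact test over genes at 1 RPKM or more in WT and with a Mantel-Haenszel odds ratio over 10 expression deciles. Peaks, overlaps and figures were computed with Python 3.11.15, numpy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

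Genes were named by rule. In each comparison these were the 10 largest log2 changes in each direction among passing genes with a mean of at least 10 CPM (1 RPKM for KO) and no overlap between groups, skipping predicted genes. From each called list, or list with at least 2 passing members, up to 4 members with the smallest p were added. Where fewer than 3 genes passed, the 5 smallest p-values were named as not passing. For CLIP the rule took the 10 genes with the most peaks, the 10 highest peaks and list members with peaks. Every exception is said to be chosen after its values were seen.

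Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, no filter, a mean of at least 10 CPM, the replicate number as a block, 1 fit for all DG libraries, other scalings, filters and offsets for RPKM, other overlap rules and backgrounds, and each library left out in turn. Alternatives added after the data were seen left out CLIP replicates, left out both ECT libraries numbered 3, took choroid plexus marker level as a covariate, used backgrounds that account for strand and left out peaks whose gene lies on another chromosome in the reference. The tests of ECT in input, ECT in RIP, the interaction and KO were run on simulated data with 200 changed genes, where 3.79 to 9.52% of calls were false in 3 of the comparisons and 0% in the interaction. The peak overlap code was right for 100% of simulated peaks. Each test was also repeated on regroupings of the same libraries, all 10 for 3 against 3 and 40 for the interaction. Those 40 were the real grouping and a random draw from the other possible ones. The precision of a CPM value near 0 is limited by depth, and 3 counts stand for the upper limit of a count of 0. Duplicates were searched for among DG libraries of the same group and none was found. A planned search of peaks for the m6A sequence motif needs a genome sequence and was not analysed here. Results of some genes are not reported here.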

Results

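The series examined how N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, and Ythdf1, a cytoplasmic protein that binds this mark through its YTH domain, relate to transcripts of the adult mouse hippocampus. C57BL/6J mice aged 8 to 16 weeks were used, with 3 replicates in every group. Crosslinking and immunoprecipitation (CLIP) mapped the RNA sites bound by Ythdf1 in wild-type hippocampus, and CLIP with an m6A antibody mapped the modified sites in hippocampal poly(A) RNA. mRNA-seq compared 3 hippocampal libraries labelled wild type (WT) with 3 labelled Ythdf1 knockout (KO). In the dentate gyrus (DG), the hippocampal field of granule neurons, poly(A) RNA (input) and RNA recovered with the m6A antibody (m6A-RIP) were sequenced after electroconvulsive treatment (ECT), a current that evokes a generalised seizure, and after mock treatment. By their labels the ECT inputs were taken 1 h after treatment, while the RIP labels give no time.

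The DG count table covered 24411 genes. Total counts were 15014000, 28113049 and 16083419 in the mock inputs, 19928242, 14194956 and 20510142 in the ECT inputs, 17408412, 17600492 and 17664730 in the mock RIP and 13555180, 34745171 and 19083430 in the ECT RIP libraries. A count of 0 allows up to 0.0863 CPM in the deepest and 0.221 CPM in the shallowest of them, a limit that covers counting error only. The WT and KO table gave RPKM for 24667 genes, and 12955 to 13231 of them were at 1 RPKM or more in each library; its read totals are unknown. The Ythdf1-CLIP lists held 9353, 11727 and 13327 peaks and the m6A-CLIP lists 25644, 35106 and 32819. Because the labels do not say that replicates came from separate animals, edgeR and limma p-values measure the spread between these samples, which may be technical. Camera p-values compare the genes of a set with other genes, at a preset or estimated correlation between genes. Fisher p-values and the intervals of shares and odds ratios count genes or peaks as independent units and hold no spread between samples.

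The first question was which transcripts Ythdf1 binds and where. Its peaks with a gene name lay mostly in 3′ untranslated regions (UTRs), in genes of high expression. Among the 3552 high-confidence Ythdf1-CLIP peaks, 2550 carried a gene name, and of these 57.6% were in 3′ UTRs, 24.0% in coding sequence, 8.86% in introns, 5.41% in noncoding RNA and 3.10% in 5′ UTRs. The 1044 genes with a peak had a median WT expression of 47.8 RPKM, against 9.03 RPKM for expressed genes in neither CLIP list. Peak counts per gene were not adjusted for expression or strand, and 845 of the 1044 genes had their peaks on the minus strand. Malat1, a nuclear noncoding RNA, held the most peaks (30). Other transcripts with many peaks were the mRNAs of the calcium sensor of vesicle release Syt1 (23), the calcium pump Atp2b2 (22), the glutamate transporter Slc1a2 (20), Ncdn (19), the NMDA receptor subunit Grin2b (17), the kinesin Kif5a (17) and Arf3 (16), with 17 in the transcript 2900097C17Rik. Presynaptic genes were hit most often: 17 of 24 expressed members had a peak (odds ratio 29.8, Fisher's exact test, Benjamini-Hochberg adjusted p 4.39e-13). So did 15 of 40 glutamate receptor and postsynaptic scaffold genes (odds ratio 7.34, Fisher adjusted p 1.21e-06) and 7 of 21 voltage-gated ion channels (odds ratio 6.07, Fisher adjusted p 0.00514). The odds ratios of lists were not adjusted for expression or strand, so they do not separate a preference of Ythdf1 from high expression. In mm10 coordinates, a 3′ UTR peak of the synaptic kinase gene Camk2a spanned chromosome 18, 60987807 to 60987869. A 3′ UTR peak of the AMPA receptor subunit gene Gria1 spanned chromosome 11, 57329450 to 57329501, and a 3′ UTR peak of Syt1 spanned chromosome 10, 108497837 to 108497880. Activity-regulated genes had a peak about as often as the 1001 of all 13089 expressed genes, in 2 of 22 transcription factors and 2 of 29 effectors (odds ratios 1.21 and 0.894, Fisher adjusted p 0.982 and 1).

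The authors' score of a peak is its number of mutations, and in both assays a few peaks held much of the total. The 10 highest of the high-confidence Ythdf1-CLIP peaks held 47.8% of all mutations, and those of m6A-CLIP held 75.0%. The ribosomal RNA precursor Rn45s led both lists among named genes, with 101636 mutations at chromosome 17, 39848062 to 39848194 (noncoding) in Ythdf1-CLIP and 513778 at 39848096 to 39848121 in m6A-CLIP. Of the 10 highest Ythdf1-CLIP peaks, 9 had no gene name, and the first lay on chromosome 3, 5860655 to 5860685, with 122122 mutations. Peaks were 26 to 27 nucleotides long in the median, and the high-confidence ones had median scores of 7 in Ythdf1-CLIP and 10 in m6A-CLIP. Repeatability was moderate: 27.5 to 38.0% of the peaks of a Ythdf1-CLIP replicate overlapped a peak in each of the other lists by at least 1 bp on the same strand (32.1% on average), and 32.7 to 44.3% did so in m6A-CLIP (37.3% on average). In each assay the high-confidence list was exactly the set of replicate 1 peaks shared with the other lists.

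The m6A map covered 3451 genes, and its peaks with a gene name lay mostly in 3′ UTRs and coding sequence. Of the 9939 high-confidence peaks with a gene name, 45.4% were in 3′ UTRs, 40.7% in coding sequence, 6.35% in 5′ UTRs and 3.02% in introns. Ddn, which encodes the dendritic protein dendrin, held the most (41). Next came the active zone gene Bsn (35), Lingo1 (32), Ncdn and Tmem151b (26 each), Gpr37l1 and Jph4 (23 each), and Camk2b, Nfe2l1 and Snph (22 each). These counts do not account for transcript length, expression or strand, and 2723 of the 3451 genes had their peaks on the minus strand. Of the m6A-CLIP peaks whose gene is in the reference, 79 of 9421 lay on another chromosome than their gene, and of the Ythdf1-CLIP peaks 0 of 2483. Without them 32 genes had no m6A-CLIP peak left, 1 of them in the fixed lists (Ndufa1, named after its values were seen), and the list counts that follow did not change. m6A-CLIP peaks were present in 26 of 40 glutamate receptor and postsynaptic genes (odds ratio 5.74, Fisher adjusted p 1.64e-06), 16 of 21 ion channel genes (odds ratio 9.88, Fisher adjusted p 1.08e-05). They were also present in 16 of 24 presynaptic genes (odds ratio 6.17, Fisher adjusted p 0.000119) and 15 of 24 chromatin regulators and cofactors (odds ratio 5.14, Fisher adjusted p 0.000506). These odds ratios were not adjusted for expression, strand or transcript length either. High 3′ UTR peaks included those of Zfp91 at chromosome 19, 12769606 to 12769624 (3394 mutations) and of Nap1l5 at chromosome 6, 58906066 to 58906128 (2683). The potassium channel gene Kcnj4 had one at chromosome 15, 79484257 to 79484318 (1933), Camk2b at chromosome 11, 5970100 to 5970122 (1793), and Basp1 a coding peak at chromosome 15, 25364380 to 25364406 (2664). Arc, an activity-regulated synaptic gene, had a 3′ UTR peak at chromosome 15, 74671002 to 74671095 (198), and Ythdf1 mRNA itself a coding peak at chromosome 2, 180911213 to 180911240 (12).

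Ythdf1 sites and m6A sites met more often than genomic positions 1000 bp away did. A high-confidence m6A-CLIP peak overlapped 1061 of the 3552 Ythdf1-CLIP peaks, or 29.9% (exact binomial 95% interval 28.4 to 31.4%), against 3.66% and 4.70% when the same peaks were shifted by 1000 bp down or up. A shift along the genome can leave the exon or the transcript, so the shifted shares are not a chance level for sequence that both assays can recover. The share was 34.5% among 3′ UTR peaks, 37.5% in coding sequence and 15.9% in introns. It was 27.9% among 136 mitochondrial peaks and 23.2% among 866 nuclear peaks without a gene name, so the overlap was not confined to nuclear mRNAs. The 3′ UTR peaks of Camk2a and Gria1 were examples, as their m6A-CLIP peaks spanned chromosome 18, 60987822 to 60987857, and chromosome 11, 57329477 to 57329516. Gene by gene, 754 of the 1044 Ythdf1-CLIP genes (72.2%) were also m6A-CLIP genes. Over 13089 expressed genes the odds ratio was 11.6 (95% interval 9.99 to 13.5, Fisher's exact test, two-sided, p 4.25e-270), with 749 genes in both sets where 246 were expected. Part of this went with expression, since the odds ratio was 7.65 (6.53 to 8.96) over deciles of WT RPKM. It was 5.85 (5.03 to 6.81) among the 8275 expressed genes with a peak in any replicate list, a background not matched for expression. Peaks fell mostly on the minus strand in both assays (81.4% and 87.3% of nuclear high-confidence peaks), and with genes stratified by strand the odds ratio was 5.29 (4.53 to 6.18), and 4.65 (3.41 to 6.34) on the plus strand alone; the backgrounds behind 5.85, 5.29 and 4.65 were chosen after the data were seen. Overlap by position moved with its definition, to 19.2% when 50% of the Ythdf1 peak had to be covered and to 36.8% for peak centers within 50 bp.

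**Figure D1:**
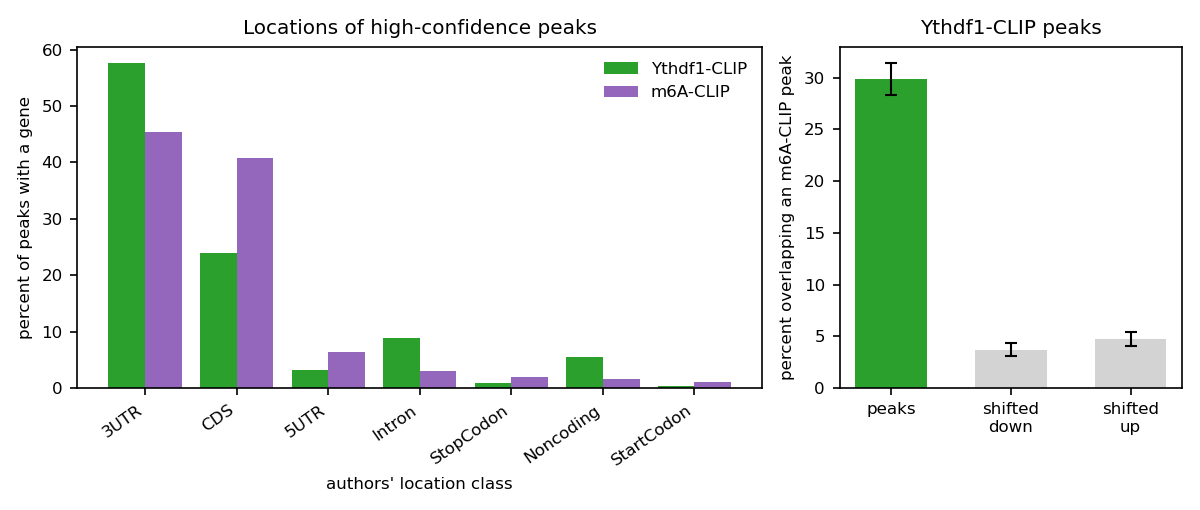
Left, percent of high-confidence peaks with a gene name (y axis) in each of the authors' location classes (x axis) for Ythdf1-CLIP and m6A-CLIP; right, percent of high-confidence Ythdf1-CLIP peaks that overlap an m6A-CLIP peak, as mapped and after a shift of 1000 bp in either direction, with exact binomial 95% intervals as error bars. The share in 3′ UTRs was 57.6% for Ythdf1-CLIP and 45.4% for m6A-CLIP, and 29.9% of Ythdf1-CLIP peaks overlapped against 3.66% and 4.70% after the shifts.

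A separate antibody experiment, m6A-RIP of whole transcripts in mock DG, sorted genes by how much more or less the antibody recovered than of the typical gene. Lists of glutamate receptors, ion channels and chromatin regulators were called enriched and those of the ribosome and oxidative phosphorylation depleted, though 0 lists were called with an estimated correlation. Short transcripts as a class were recovered less, with a median log2 ratio of −1.69 in the shortest decile of length and 0.83 in the longest. Kcnj4 stood at 2.23 ± 0.932 CPM in input and 39.7 ± 11.1 CPM in RIP (mean ± SD, n = 3, log2 ratio 4.15, SE 0.43, edgeR adjusted p 1.66e-06). The receptor adaptor Garem rose to 209.5 ± 52.7 from 14.4 ± 2.79 CPM (3.86) and the adhesion gene Clmp to 198 ± 23.7 from 16.4 ± 2.46 CPM (3.59). At the other end, the ribosomal gene Rps14 went from 435 ± 49.2 to 15.9 ± 9.17 CPM (log2 ratio −4.77, SE 0.38, edgeR adjusted p 2.09e-07). Usmg5, a small ATP synthase subunit, had a log2 ratio of −4.73, and the tetraspanin Cd81 one of −4.58. In all, 8082 of 15335 genes passed at an absolute log2 ratio of at least 1, 3950 enriched and 4132 depleted. Of these, 98.9% did not overlap between groups, against 70.4% of all genes and 10% by chance. Ythdf1 itself had a log2 ratio of 0.71 (edgeR adjusted p 0.0465), under that minimum. Input and RIP also differ in 1 against 2 rounds of poly(A) selection, so the ratio holds both. The alternatives gave 6378 to 9046 genes, the latter without the minimum.

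Of the fixed lists, 8 were called in mock RIP over input, and none of the 8 was lost on leaving out any library. All 38 tested oxidative phosphorylation genes were depleted (median log2 ratio −3.10, camera adjusted p 3.78e-17) and 79 of 81 ribosomal protein genes were (median −3.51, camera adjusted p 2.10e-26). The same 38 and 79 passed adjusted over the list alone. Ndufa4, a respiratory chain subunit, had 700 ± 125 CPM in input and 52.6 ± 18.0 in RIP. Translation factors went the same way, 16 depleted and 3 enriched of 26 (19 adjusted over the list alone, camera adjusted p 0.00132), including Eif3e (−4.36). Glutamate receptor and postsynaptic genes were enriched in 25 of 40 cases and depleted in 4 (29 adjusted over the list alone, camera adjusted p 8.51e-05), among them the adhesion molecule Nlgn1 (2.90), Gria1 (2.37) and Grm5 (2.11). Ion channels were enriched in 12 of 20 cases and depleted in 1 (13 adjusted over the list alone, camera adjusted p 0.000835), with Kcna1 at 2.42 and Kcnd2 at 1.98. Chromatin regulators had 16 enriched and 3 depleted of 24 (19 adjusted over the list alone, camera adjusted p 0.000772), with the remodelling subunit Arid1b and the acetyltransferase gene Crebbp both at 3.21. Activity-regulated transcription factors had 11 enriched and 1 depleted of 25 (14 adjusted over the list alone, camera adjusted p 0.00445), with Jun at 3.24, and the MAPK feedback genes 8 of 12 enriched (8 adjusted over the list alone, camera adjusted p 0.0190). With an estimated correlation none of these 8 passed (camera adjusted p 0.462 for the transcription factors and 0.447 for the others).

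Other lists went both ways and were not called. Presynaptic genes had 6 enriched and 10 depleted of 24 (16 adjusted over the list alone, camera adjusted p 0.395). Nrxn3 was at 2.18, and Syt1 fell from 1286 ± 122 to 224 ± 15.3 CPM (−2.52). Activity-regulated effectors had 16 enriched and 3 depleted of 31 (camera adjusted p 0.0788), with Bdnf at 2.70, and the m6A machinery 8 and 4 of 20 (camera adjusted p 0.369), with the reader Ythdf2 at 2.18 and Hnrnpc at −2.89. Neuropeptide genes had 2 enriched and 7 depleted of 16 (camera adjusted p 0.0893, Npy −2.85). Among cell type markers, enriched and depleted members were 7 and 3 of 12 for granule neurons (camera adjusted p 0.0634), 7 and 1 of 13 for newborn neurons (0.0788), and 2 and 8 of 13 for interneurons (0.182, Gad1 −3.38). They were 3 and 6 of 12 for CA pyramidal and mossy cells (camera adjusted p 0.294), 5 and 5 of 12 for astrocytes (0.993), 4 and 3 of 13 for oligodendrocytes (0.625), 3 and 6 of 12 for microglia (0.239), 3 and 5 of 13 for vascular cells (0.625) and 0 of 11 for choroid plexus and ependyma (0.855). For astrocytes the median was −0.14 while the test pointed up. Stress genes had 6 and 1 of 14 (0.294), clock genes 2 and 3 of 16 (0.855, median −0.03, test upward), and the only tested blood gene was depleted (−3.04).

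**Figure D2:**
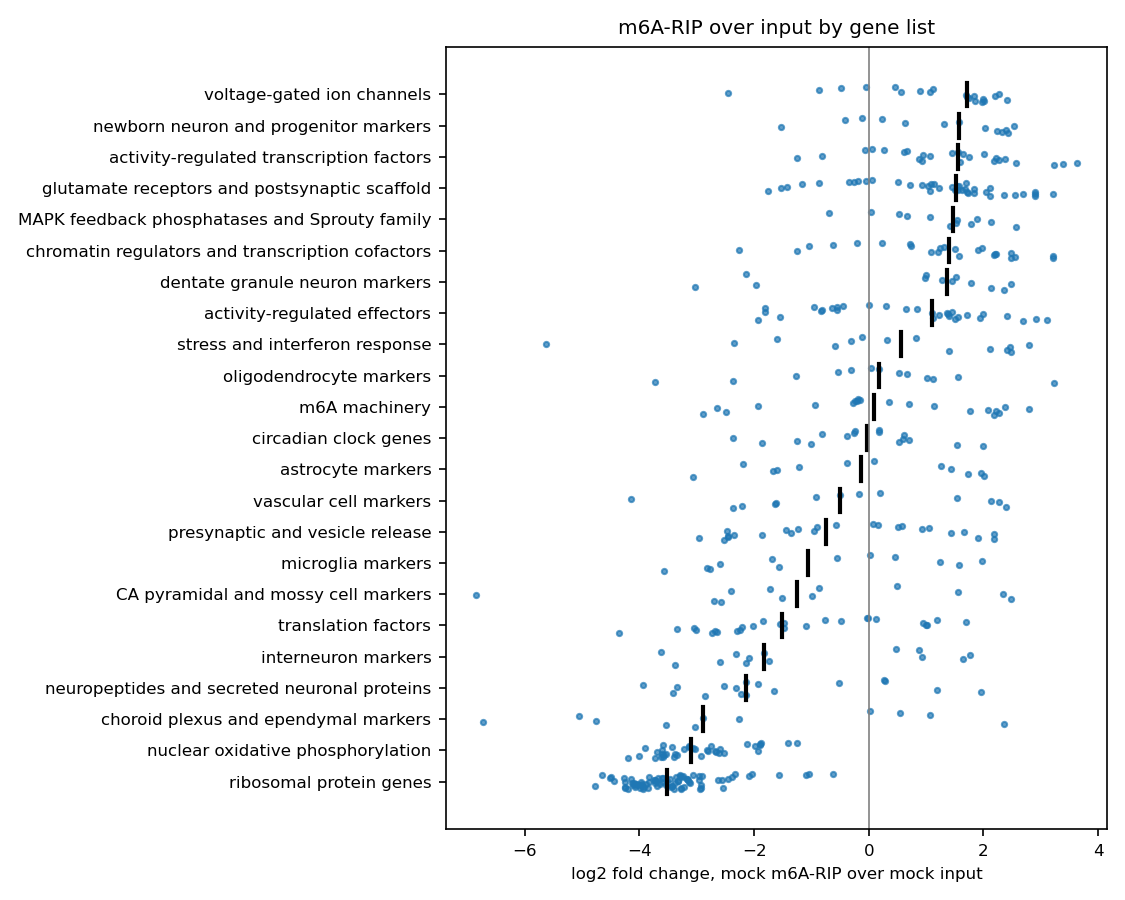
Log2 fold change of mock m6A-RIP over mock input (x axis) for members of each fixed list with at least 5 tested genes (y axis); each point is 1 gene from an edgeR fit on 3 libraries per group and each black bar the list's median. Medians ran from −3.51 for ribosomal protein genes to 1.71 for voltage-gated ion channels.

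The 2 m6A experiments were then set side by side. Genes of the hippocampal m6A-CLIP list were recovered better in DG: over 3159 such genes the median log2 ratio of RIP over input was 0.78, against −0.24 for the other 12176, a difference of 1.01 (camera p 1.02e-05, p 0.116 with an estimated correlation). Of the listed genes 1363 were enriched and 643 depleted. Longer transcripts were enriched more (Spearman's rho 0.282 across genes, which are not independent replicates), with median lengths of 3755 nucleotides among enriched and 2278.5 among depleted genes, and after adjustment for length the difference was 0.743. Genes of the Ythdf1-CLIP list did not stand apart in the same comparison (difference 0.00, camera p 0.926). The difference was 0.27 for genes in all 3 Ythdf1-CLIP replicate lists (camera p 0.268) and 0.41 for genes in both CLIP lists (camera p 0.191). Recovery fell with input level (Spearman's rho −0.231 across genes). The same mock inputs enter both values, so part of this fall can arise by construction. Ythdf1-CLIP genes were highly expressed, and the comparison was not adjusted for that, so it does not show that they carry no more m6A.

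The third comparison asked how mRNA levels differ without Ythdf1, a protein held to promote the translation of its targets. In the libraries labelled KO, almost no transcript differed from WT beyond the spread between libraries. Ythdf1 itself was at 22.4, 22.4 and 22.7 RPKM in the WT and at 22.6, 21.6 and 23.7 RPKM in the KO libraries (chromosome 2, 180904377 to 180920936, log2 fold change 0.01, limma adjusted p 0.999). A value over the whole gene does not show which part is deleted, so this neither bears out nor contradicts the labels. In the DG, Ythdf1 was at 31.1, 45.4 and 57.5 CPM in mock input, 34.4, 35.1 and 21.3 in ECT input, 58.6, 85.0 and 62.8 in mock RIP and 83.1, 91.6 and 142 in ECT RIP. A single entry of 13183 passed, the microRNA entry Mir546, at 12.8, 28.3 and 18.9 RPKM in WT and at most 0.064 RPKM in KO (log2 fold change of RPKM + 1 of −4.30, SE 0.25, limma adjusted p 0.00751). It lies at chromosome 10, 126998440 to 126998560, inside Ctdsp2, whose own log2 fold change was 0.00, and such a short entry inside another gene is uncertain in poly(A) RNA. At unadjusted p under 0.05 there were 581 genes where 659.15 were expected, and 11.7% of genes did not overlap between groups, against 10% by chance. On simulated data the same test recovered 71.6% of genes changed 2-fold and 25.4% of those changed 1.5-fold. The count was 12 without WT replicate 1, 4 without KO replicate 2, and 0 without WT replicate 3, KO replicate 1 or KO replicate 3 (limma adjusted p of Mir546 0.0808, 0.0794 and 0.114). It was also 0 when choroid plexus marker level entered as a covariate added after the data were seen.

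The next smallest p-values belonged to a pair of neighbouring genes. Alad, a haem synthesis enzyme, was at 4.69 ± 0.349 RPKM in WT and 9.24 ± 0.171 RPKM in KO libraries (mean ± SD, n = 3, log2 0.85, SE 0.08, limma adjusted p 0.0840, chromosome 4, 62505984 to 62520063). Hdhd3 beside it was at 6.23 ± 1.25 and 14.6 ± 0.198 RPKM (log2 1.12, SE 0.13, limma adjusted p 0.247, 62499054 to 62502200). Dnali1 (0.83, limma adjusted p 0.325) and Sln, a regulator of the calcium pump (1.36, limma adjusted p 0.341), came after them. None of these passed over all genes.

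**Figure D3:**
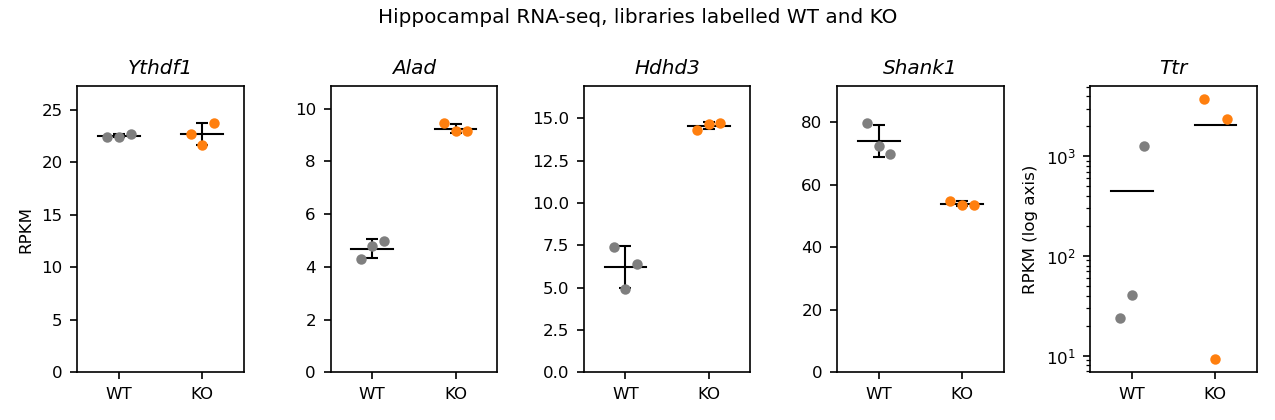
RPKM (y axis, log axis for Ttr) of 5 genes in the hippocampal libraries labelled WT (grey) and KO (orange); points are libraries, lines are means and error bars, where drawn, are SDs, n = 3 per group. Ythdf1 lay between 21.6 and 23.7 RPKM in all 6 libraries, and Ttr ranged from 9.17 to 3745 RPKM without following the labels.

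Of the fixed lists 8 were called in the libraries labelled KO, though no member passed over all genes. The choroid plexus list had the largest median, and the other 7 had medians between −0.19 and −0.03. Choroid plexus and ependymal markers were higher in 13 of 13 cases (3 adjusted over the list alone, the ciliated cell genes Foxj1, Ccdc153 and Tmem212, median 1.33, camera adjusted p 5.33e-08, 0.760 with an estimated correlation). Their main member Ttr, the transthyretin of choroid plexus, was at 24.0, 40.7 and 1266.5 RPKM in the WT and 3745, 9.17 and 2377 RPKM in the KO libraries. Lower values prevailed in ribosomal protein genes (76 of 83, 0 adjusted over the list alone, median −0.16, camera adjusted p 0.000780, 0.816 with an estimated correlation) and in glutamate receptor and postsynaptic genes (30 of 40, 1 adjusted over the list alone, median −0.07, camera adjusted p 0.00329, 0.760 with an estimated correlation). The same held, with values in the same order, for astrocyte markers (11 of 12, 0, −0.18, camera adjusted p 0.00407, 0.760) and vascular markers (12 of 13, 0, −0.17, camera adjusted p 0.00978, 0.760). It also held for neuropeptides (11 of 16, 0, −0.19, camera adjusted p 0.0129, 0.760), translation factors (23 of 26, 0, −0.07, camera adjusted p 0.0397, 0.777) and chromatin regulators (16 of 24, 0, −0.03, camera adjusted p 0.0397, 0.793). The postsynaptic member that passed adjusted over the list alone was the scaffold gene Shank1, at 73.9 ± 5.08 RPKM in WT and 53.9 ± 0.790 in KO (log2 −0.45, limma adjusted p 0.609 over all genes).

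Most of these list calls depended on single libraries. The choroid plexus call alone passed in the same direction with any library left out. Ribosomal protein genes, called lower, were called higher without WT replicate 1 (camera adjusted p 8.91e-12), and so were oxidative phosphorylation genes (1.16e-09), so the direction of both rested on that library. With the choroid plexus level as a covariate the camera adjusted p was 0.675 for the ribosomal and neuropeptide lists, 0.497 for translation factors, 0.120 for astrocyte and 0.0592 for vascular markers. Leaving out WT replicate 1 gave 0.633 for astrocyte, 0.766 for vascular, 0.382 for neuropeptide and 0.606 for translation genes, the last with an upward direction. The glutamate list was lost without WT replicate 2 (0.258), WT replicate 3 (0.0990) or KO replicate 1 (0.0672), and the chromatin list without WT replicate 2 (0.834), WT replicate 3 (0.471), KO replicate 1 (0.0764) or KO replicate 2 (0.0711). KO replicate 1 also decided the neuropeptide (0.0672) and translation (0.0676) calls, KO replicate 2 the translation (0.0711) and vascular (0.0704) calls and KO replicate 3 the neuropeptide (0.0501) and translation (0.0652) calls. Other lists were not called, with camera adjusted p of 0.0574 for oxidative phosphorylation (36 of 39 lower), 0.102 for microglia, 0.193 for activity-regulated transcription factors, and 0.207 for CA pyramidal and mossy cells. They were 0.224 for presynaptic genes, 0.270 for MAPK feedback genes, 0.271 for interneurons, 0.375 for stress and for clock genes, 0.522 for ion channels and oligodendrocytes, 0.609 for the m6A machinery and granule neurons, 0.653 for blood cells and 0.657 for activity-regulated effectors, with newborn neurons between microglia and the transcription factors. For ion channels the median was −0.02 and the mean 0.01, and for granule neurons the median was −0.01 while the test pointed up.

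Transcripts bound by Ythdf1 were nearly level with the rest in the libraries labelled KO. The 1002 expressed Ythdf1-CLIP genes had a median log2 change lower than that of other genes by 0.018, a difference of −0.018 that passed at camera p 0.0390 and did not with an estimated correlation (p 0.423). It was lost without WT replicate 2 (0.0112, p 0.973), WT replicate 3 (−0.00864, p 0.180) or KO replicate 1 (−0.00647, p 0.372) and with choroid plexus level as a covariate (−0.011, p 0.204), and larger without WT replicate 1 (−0.0567, p 2.71e-06) or KO replicate 2 (−0.0287, p 0.00728). The m6A-CLIP genes differed by −0.00785 (camera p 0.305). With 1 library left out this ran from −0.0501 without WT replicate 1 (p 0.000142), where alone p was under 0.05, to 0.0213 without WT replicate 2 (p 0.413).

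The fourth comparison followed DG transcripts after ECT, first in input. Transcripts induced by neuronal activity were much higher 1 h after ECT. Atf3, a transcription factor of stress and injury responses, rose from 0.699 ± 0.609 to 121 ± 52.9 CPM (mean ± SD, n = 3 libraries per group, log2 fold change 7.38, SE 0.60, edgeR adjusted p 0.000358). Inhba, which encodes an activin subunit, rose from 4.89 ± 0.897 to 365 ± 164 CPM and the synaptic gene Arc by a log2 fold change of 4.41 (edgeR adjusted p 0.000405). Fos rose from 10.8 ± 0.690 to 192 ± 109 CPM, and the prostaglandin synthase gene Ptgs2 from 57.4 to 1079 CPM. Bdnf, a neurotrophin, rose from 160 ± 12.6 to 1247 ± 291 CPM (2.96, SE 0.18, edgeR adjusted p 0.000154), and the prohormone convertase gene Pcsk1 from 12.0 ± 1.62 to 132 ± 21.3 CPM. Transcripts that fell included the presynaptic glutamate receptor Grm2, from 26.1 ± 3.30 to 3.35 ± 0.909 CPM (−2.95, SE 0.26, edgeR adjusted p 0.000474). Others were the neurotrophin Ntf3, from 86.6 ± 14.2 to 17.0 ± 8.42 CPM, the small GTPase gene Rasl10a (−2.58) and C1ql2, which encodes a synaptic protein of mossy fibres, from 29.9 ± 4.92 to 9.35 ± 2.20 CPM.

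In edgeR's quasi-likelihood test 958 of 14530 genes passed, 591 higher and 367 lower, with median log2 changes of 1.10 and −1.07; 340 and 216 of them changed at least 2-fold. All 958 had no overlap between groups, against 32.0% of all genes and 10% by chance. On simulated data the test recovered 77.3% of genes changed 4-fold and 25.4% of those changed 2-fold, and DESeq2 called 2026. The count was 634 without mock input 1, 142 without mock input 2, 391 without mock input 3, 417 without ECT input 1 and 317 without ECT input 2. Of 57 named genes that passed, 28 passed whichever library was left out, among them every gene of the paragraph above. Choroid plexus transcripts were high in a single library, ECT input 3, with Ttr at 31760 CPM against at most 24.3 in the other inputs; without it 843 genes passed, 698 of the 958 among them.

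**Figure D4:**
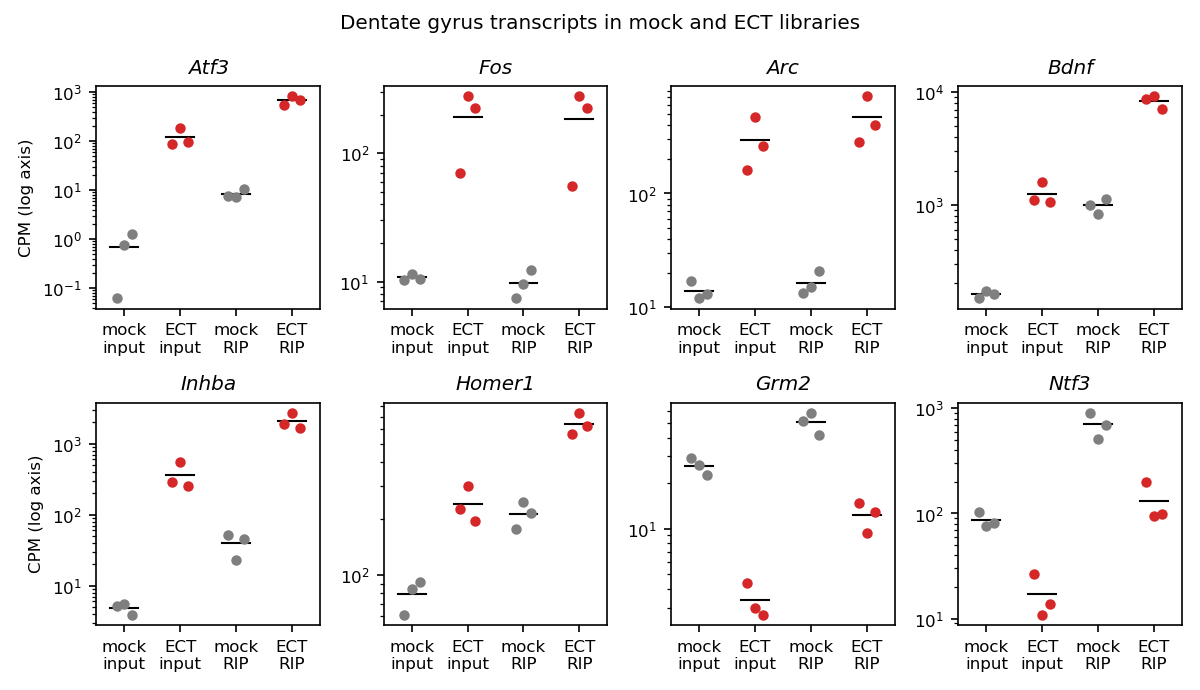
CPM (y axes, log) of 8 DG transcripts in mock (grey) and ECT (red) libraries of input and m6A-RIP; points are libraries, n = 3 per group, and lines are means. Atf3, Fos, Arc, Bdnf, Inhba and Homer1 were higher and Grm2 and Ntf3 lower in all 3 ECT than in all 3 mock libraries of each kind.

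By list, 16 of 25 activity-regulated transcription factors rose and none fell (20 adjusted over the list alone, median 1.98, camera adjusted p 1.14e-16, adjusted p 0.189 with an estimated correlation). Among them were the AP-1 member Fosl2 at 3.23 and the nuclear receptor Nr4a2 at 3.06. Among activity-regulated effectors 24 of 31 rose (30 adjusted over the list alone, median 2.41, camera adjusted p 6.02e-30, 0.189 with an estimated correlation), including the postsynaptic Homer1 (1.59) and the G protein regulator Rgs2 (2.41). MAPK feedback genes had 7 higher and 1 lower of 12 (9 adjusted over the list alone, camera adjusted p 0.000427, 0.211 with an estimated correlation). The phosphatases Dusp6 and Dusp4 were at 1.78 and 2.18, and Spry1, named after its value was seen, was the one that fell (−1.51). Stress genes had 4 of 13 higher (4 adjusted over the list alone, camera adjusted p 0.00347, 0.189 with an estimated correlation). They were the endoplasmic reticulum chaperone Hspa5, from 430 ± 5.64 to 1352 ± 215 CPM, the glucocorticoid-induced Tsc22d3 (1.87), and the heat shock genes Dnajb1 (1.11) and Hsph1 (0.60, edgeR adjusted p up to 0.159 with 1 library left out). Scg2 (1.56) and Penk (1.90) rose among 15 neuropeptide genes (2 adjusted over the list alone, camera adjusted p 0.0119, 0.229 with an estimated correlation, 0.0721 without mock input 1). Clock genes had 3 higher, including Per1 (1.59) and Per2 (1.73), and 2 lower of 16 (8 adjusted over the list alone, camera adjusted p 0.275). Without mock input 2 neither passed (edgeR adjusted p 0.113 and 0.0676).

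Lists of cell type markers with at least 5 tested genes, choroid plexus aside, had medians of at most 0.61 in size. Granule neuron markers were lower in 11 of 12 cases, 3 of them past the test (C1ql2, Dsp at −1.04 and Trpc6 at −0.85, 7 adjusted over the list alone, 6 lower and 1 higher, median −0.61, camera adjusted p 0.000427, 0.431 with an estimated correlation). Higher values prevailed in interneuron markers (11 of 13, 1 passed, the receptor kinase Kit, from 76.7 to 171 CPM, 1 adjusted over the list alone, camera adjusted p 0.0170, 0.211 with an estimated correlation), and oligodendrocyte markers (12 of 13, 0 passed, 0 adjusted over the list alone, camera adjusted p 0.0119, 0.473). The same held for astrocyte markers (9 of 12, 1 passed, the connexin Gjb6 at 0.82, 2 adjusted over the list alone, camera adjusted p 0.0474, 0.342). The interneuron call was lost without mock input 1 (0.0721) or ECT input 1 (0.0787) and the astrocyte call without ECT input 1 (0.0969) or ECT input 2 (0.0597). Choroid plexus markers had a median of 6.17 with 0 of 7 past the test (4 adjusted over the list alone, camera adjusted p 0.0474, 0.611 with an estimated correlation), and adjusted p was 0.410 without ECT input 3, 0.131 without mock input 1 and 0.0906 without mock input 2. Without mock input 2, Dsp (edgeR adjusted p 0.0882), Trpc6 (0.128) and Gjb6 (0.122) did not pass. CA pyramidal and mossy cell, newborn neuron, microglia and vascular markers were not called (camera adjusted p 0.233, 0.824, 0.827 and 0.824, 1, 1, 0 and 0 passed), and the blood gene tested was at 1.03 without passing.

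Among the remaining lists, all 3 m6A machinery genes that passed were higher, Hnrnpa2b1 at 0.68 with Hnrnpc and Rbm15, of 20 (5 adjusted over the list alone, camera adjusted p 0.0476, 0.491 with an estimated correlation), while Ythdf1 was at −0.56 (SE 0.27, edgeR adjusted p 0.221). Translation factors had 2 higher of 26, Eif3c (0.67) and Eif2s1 (0.52) (4 adjusted over the list alone, camera adjusted p 0.0476, 0.491 with an estimated correlation). Leaving out mock input 1, mock input 2, ECT input 1 or ECT input 2 raised the adjusted p to 0.105, 0.0606, 0.193 and 0.165 for the m6A machinery and to 0.131, 0.129, 0.144 and 0.170 for translation factors. With the replicate number as a block they were at 0.0581 and 0.0631. Oxidative phosphorylation genes were higher in 35 of 38 cases by little (median 0.23, 0 passed, 0 adjusted over the list alone, camera adjusted p 0.00111, 0.754 with an estimated correlation, 0.130 without mock input 1). Glutamate receptor and postsynaptic genes went both ways, 3 higher and 3 lower of 40 (8 adjusted over the list alone, camera adjusted p 0.824, median 0.04, mean −0.06), the latter with Grm2 and Shank3 (−0.97). Chromatin regulators had 3 higher of 24, Tet3 (1.51), Tet2 (1.80) and Kdm6b (2.19) (3 adjusted over the list alone, camera adjusted p 0.865, median −0.06, mean 0.14). Ion channels had 1 higher, Kcna1 (0.86), and 1 lower, Kcnd2 (−0.78), of 20 (2 adjusted over the list alone, camera adjusted p 0.805). Presynaptic genes had 1 higher of 24 (3 adjusted over the list alone, camera adjusted p 0.824) and ribosomal genes 0 of 81 (0 adjusted over the list alone, 0.213). Grm2 aside, each gene named in this paragraph that passed lost its call without mock input 2, at edgeR adjusted p from 0.0700 (Tet3) to 0.196 (Rbm15).

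The same treatment was then compared in m6A-RIP, where the strongest changes again concerned activity-regulated genes. Atf3 rose from 8.53 ± 1.84 to 693 ± 138 CPM (mean ± SD, n = 3, log2 6.34, SE 0.29, edgeR adjusted p 2.16e-06). Fosb rose from 1.69 ± 0.418 to 186 ± 108 CPM, Inhba from 40.6 ± 15.4 to 2090.3 ± 574 CPM, Arc from 16.4 ± 3.95 to 465 ± 224 CPM and Bdnf from 987.5 ± 145 to 8341 ± 1145 CPM (3.08, SE 0.20, edgeR adjusted p 2.38e-05). The synaptic pentraxin Nptx2 (4.73) and the protocadherin Pcdh8, from 74.1 ± 12.2 to 922 ± 56.3 CPM, rose as well. Ntf3 fell from 708.5 ± 197 to 131 ± 59.1 CPM (−2.44, SE 0.33, edgeR adjusted p 0.00327). Grm2 fell from 50.4 to 12.3 CPM, the exchange factor gene Tiam2 from 156 ± 38.4 to 30.3 ± 7.47 CPM and the ubiquitin ligase gene Fbxo32 from 51.0 ± 11.4 to 11.4 ± 0.515 CPM. In edgeR's test 272 of 14116 genes passed, 205 higher and 67 lower (median log2 1.61 and −1.36), all without overlap between groups, against 23.6% of all genes and 10% by chance; 2361 were at unadjusted p under 0.05. On simulated data it recovered 33 of 66 genes changed 4-fold, and DESeq2 called 1080. The count was 64 without mock RIP 1, 149 without mock RIP 2, 76 without mock RIP 3 and 113 without ECT RIP 2, and every gene of this paragraph passed with any of the 6 libraries left out. Choroid plexus transcripts were again high in a single library, ECT RIP 3 (Ttr 5373 CPM against at most 2.36 in the others), without which 253 genes passed, 199 of the 272 among them.

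Lists of activity-regulated genes rose in RIP as in input. The ribosomal and presynaptic lists were called in RIP and not in input, and both were called in the interaction (adjusted p 0.929 with an estimated correlation). There the ribosomal call was lost without ECT RIP 1 (0.533) and the presynaptic call without ECT RIP 2 (0.289) or ECT input 3 (0.0935). Oligodendrocyte, astrocyte and m6A machinery lists were called in input and not in RIP, a difference that did not pass in the interaction (camera adjusted p 0.129, 0.794 and 0.794). Activity-regulated transcription factors had 14 of 25 higher (21 adjusted over the list alone, camera adjusted p 1.49e-27) and effectors 22 of 30 (27 adjusted over the list alone, camera adjusted p 1.02e-38). MAPK feedback genes had 5 of 12, Spry2 among them at 2.52 (9 adjusted over the list alone, camera adjusted p 2.25e-06). Each of these lists was at adjusted p 0.0781 with an estimated correlation. Scg2 and Penk rose among 13 neuropeptide genes (3 adjusted over the list alone, camera adjusted p 0.0231, 0.262 with an estimated correlation), a call lost without mock RIP 1 (0.0512) or ECT RIP 2 (0.0519). Hspa5 (1.82) and Hsph1 (0.97) rose among 12 stress genes (2 adjusted over the list alone, camera adjusted p 0.0152, 0.305 with an estimated correlation, 0.0772 without ECT RIP 3). Granule neuron markers had 1 lower of 12, Dsp at −1.42 (3 adjusted over the list alone, camera adjusted p 0.00531, 0.403 with an estimated correlation, 0.0528 without ECT RIP 3). Of these members Scg2 (edgeR adjusted p 0.0854), Penk (0.160), Hsph1 (0.267) and Dsp (0.0854) did not pass without mock RIP 1. No member passed in the other called lists, which had higher values. These were oxidative phosphorylation (36 of 38, median 0.58, camera adjusted p 1.51e-07, 0.459 with an estimated correlation), ribosomal protein genes (74 of 79, 0.46, 4.42e-05, 0.606), and interneuron markers (13 of 13, 0.68, 0.00124, 0.128). They were also translation factors (19 of 26, 0.33, 0.00851, 0.305), presynaptic genes (17 of 24, 0.30, 0.00964, 0.568) and choroid plexus markers (6 of 6, 6.76, 0.0139, 0.459). In this order 0, 0, 2, 0, 1 and 5 members passed adjusted over the list alone. Without ECT RIP 1 the ribosomal list was at 0.202, without ECT RIP 2 or mock RIP 3 the presynaptic list at 0.266 and 0.0563, and without ECT RIP 3 the choroid plexus list at 0.799.

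Lists not called in RIP were the m6A machinery (1 of 20 higher, 4 adjusted over the list alone, camera adjusted p 0.0646), chromatin regulators (3 of 24 higher, including Tet3 at 2.10 and Tet2 at 1.36, 5 adjusted over the list alone, 0.0799) and ion channels (2 of 20 higher, including Kcna1, 2 adjusted over the list alone, 0.196). Nor were glutamate receptor and postsynaptic genes (Homer1 higher and Grm2 lower of 40, 2 adjusted over the list alone, 0.239), newborn neurons (1 of 12 higher, 2 adjusted over the list alone, 0.268) and clock genes (1 of 16 higher, 1 adjusted over the list alone, 0.426, median −0.05, test upward). With 0 members passing, astrocytes were at 0.0518, CA pyramidal and mossy cells at 0.0615, vascular cells at 0.239 (median 0.02, test downward), oligodendrocytes at 0.582 and microglia at 0.693 (median −0.04, test upward), and the blood gene was at 1.36. Ythdf1 stood at 0.62 (SE 0.27, edgeR adjusted p 0.272). Without mock RIP 1, Kcna1 (edgeR adjusted p 0.157) and Tet2 (0.165) did not pass, while Tet3, Homer1 and Grm2 passed with any library left out.

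Changes in input and in RIP ran together. No library is shared, but ECT input and ECT RIP libraries of the same number correlated (0.207, 0.195 and 0.461), and both numbered 3 held choroid plexus transcripts, so the experiments may not be independent. Over 13601 genes tested in both, the log2 changes had Pearson's r 0.579 and Spearman's rho 0.488 across genes, which are not independent replicates. Both tests called 148 genes higher, where 8.73 were expected from independent lists, and 32 lower, where 1.79 were expected; 0 were called in opposite directions. Genes that rose in input had a median log2 change of 1.08 there and 0.89 in RIP, and those that fell −1.07 and −0.70. These genes were chosen for passing in input, which enlarges the change there, so the smaller values in RIP do not show a weaker response.

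Whether ECT changed the recovery of a transcript relative to its input was tested as an interaction over all 12 libraries, and no gene passed. edgeR called 0 of 15335 genes, with 1031 at unadjusted p under 0.05 where 766.75 were expected, and DESeq2 called 34. With the replicate number as a block edgeR called 1, Rn45s (−3.62, adjusted p 0.00162). The smallest p-values belonged to Hhip (4.56), Tsc22d3 (−1.57), Gigyf2 (−1.32), Selt (2.01) and Rb1 (1.97), each at edgeR adjusted p 0.441, and Ythdf1 was at 1.17 (edgeR adjusted p 0.722). Without ECT RIP 2 a single gene passed, Trpv2 (−6.33, edgeR adjusted p 0.0217). On simulated data this test recovered 30.3% of genes changed 4-fold and 2.99% of those changed 2-fold, so most changes of such sizes would be missed. Recovery was correlated across genes between mock and ECT libraries (r 0.843, rho 0.890). In both, 3320 genes were enriched and 3502 depleted, where 1001 and 1132 were expected from independent lists. Such values reflect differences between genes that both ratios share, so they do not show that ECT left recovery unchanged. Ifi44, named after its values were seen, was the only gene called in opposite directions (4.23 in mock, −7.21 after ECT). Of the fixed lists 3 were called, presynaptic, oxidative phosphorylation and ribosomal protein genes, each higher after ECT (camera adjusted p 0.00527, 0.000112 and 2.41e-05, each 0.929 with an estimated correlation). Without ECT RIP 1 the adjusted p was 0.476 for oxidative phosphorylation and 0.533 for ribosomal genes, and 0.0689 for the former without mock RIP 1. The presynaptic list was at 0.289 without ECT RIP 2 and at 0.0935 without ECT input 3. Activity-regulated transcription factors and effectors were not called (medians 0.23 and 0.02, camera adjusted p 0.478 and 0.808). The other lists had camera adjusted p from 0.0796 for interneuron markers and 0.129 for oligodendrocyte markers upward. Median and test differed in sign for stress genes (0.02, downward), clock genes (0.04, downward), granule neuron markers (−0.01, upward) and astrocyte markers (−0.05, upward).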

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

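The test of whether ECT changed recovery by the m6A antibody relative to input, an interaction fixed before the data were examined, differed between mock and ECT for 3 lists of genes, though for no single gene. The regroupings of libraries were planned before the result was seen, and no other tests were chosen for these lists. Presynaptic and vesicle release genes were recovered relatively better after ECT in 19 of 24 cases (median log2 0.35, camera adjusted p 0.00527), with Syn1 at 1.94, Vamp2 at 1.43, Sv2a at 0.90 and Cplx1 at 0.84, and 2 members passed adjusted over the list alone. Oxidative phosphorylation genes were so in 35 of 38 cases (median 0.35, camera adjusted p 0.000112), with Ndufa5 at 0.79 and Atp5j2 at 0.82, and ribosomal protein genes in 74 of 81 (median 0.38, camera adjusted p 2.41e-05), with Rps3 at 0.82 and Rpl7 at 0.79, and 0 members of either passed adjusted over the list alone. All 3 lists were at camera adjusted p 0.929 with an estimated correlation.

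Single libraries decided these calls. Without ECT RIP 1 the adjusted p was 0.476 for oxidative phosphorylation and 0.533 for ribosomal protein genes, without mock RIP 1 it was 0.0689 for oxidative phosphorylation, and without ECT RIP 2 or ECT input 3 it was 0.289 and 0.0935 for presynaptic genes. ECT RIP 1 had the lowest total (13555180 counts) and the fewest genes detected (14233) of the DG libraries, and whether this bears on the calls was not tested. Regrouping the libraries gave at least 3 called lists in 34 of 40 cases, the real grouping among them and the others drawn at random, so chance is not excluded for these calls. The highest other count of lists was 14, in regroupings that mix ECT and mock libraries and so can carry the effect of ECT itself. For single genes the real count is 0, which each of the 40 regroupings reaches by definition (highest other 2), so that count tells nothing.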

How the results depend on the processing

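Directions of the named genes held under almost every alternative, while counts of passing genes moved. Of the called lists, ribosomal protein genes in KO over WT turned from lower (camera adjusted p 0.000780) to higher (8.91e-12) without WT replicate 1. Translation factors there also turned upward without it (0.606). The choroid plexus list there turned from higher (camera adjusted p 5.33e-08) to lower (0.675) with the choroid plexus covariate, which was made from the same genes and so removes their change by construction. Among named genes every passing or enriched gene kept its sign, and the signs that turned belong to values near 0 or to choroid plexus and interferon genes of a single library. With 1 library left out the log2 change in RIP ran from −0.29 to 10.40 for Ttr, from −0.12 to 14.45 for Otx2 and from −0.0039 to 1.06 for Ifit1, each lowest without ECT RIP 3. Ythdf1 in KO over WT was −0.029 with choroid plexus marker level as a covariate and ran from −0.025 (without KO replicate 3) to 0.039 with 1 library left out. With 3 libraries per group, leaving out 1 leaves fewer samples to estimate the spread. For all other moves the cause was not tested. The median SE of a log2 change was 0.252 for ECT in input, 0.396 in RIP and 0.518 in the interaction.

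For ECT in input the 958 genes became 2026 with DESeq2, 359 in the fit of all 12 libraries and 142 to 843 with 1 library left out. For ECT in RIP the 272 became 1080 with DESeq2, 474 without a filter, 557 at a mean of at least 10 CPM, 874 in the fit of all 12 libraries and 64 to 253 with 1 library left out. For the interaction the 0 became 34 with DESeq2 and 0 to 1 with 1 library left out. For KO over WT the 1 became 0 with the covariate and 0 to 12 with 1 library left out. The difference of −0.018 for Ythdf1-CLIP genes there had p 0.423 with an estimated correlation, was −0.011 with the covariate and ran from −0.0567 to 0.0112 with 1 library left out. The difference of 1.01 for m6A-CLIP genes in RIP over input had p 0.116 with an estimated correlation, and 0 of the 44 list calls held with it.

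Replicate numbers are shared between groups, but libraries with the same number did not all correlate (correlations from −0.01 to 0.14 in mock and 0.20 to 0.46 in ECT between input and RIP), so they were not treated as paired. With the replicate block 453 genes passed in input, 119 in RIP and 1 in the interaction (Rn45s), and Ythdf1-CLIP genes in KO were at −0.018 with p 0.0547. List calls lost with it were the m6A machinery (0.0581) and translation factors (0.0631) in input and chromatin regulators in KO (0.0502). Calls gained were CA pyramidal and mossy cells in RIP (0.0443), activity-regulated effectors (0.04002) and granule neurons (0.0408) in RIP over input, and oxidative phosphorylation in KO (0.0308).

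The share of Ythdf1-CLIP peaks found in both other replicates, 32.1% on average, was 16.6% with 50% reciprocal overlap, and 38.0% for the upper part by mutations. For m6A-CLIP, 37.3% became 21.5% and 45.5%. With 1 replicate left out, peaks need to be found in a single other list, so the share rises by construction, to 45.6 to 46.6% and 51.0 to 52.3%. The overlap of 29.9% between the assays became 19.2% with 50% covered, 36.8% for centers within 50 bp and 25.5% for the upper part by mutations. The odds ratio of 11.6 ran from 5.29 to 21.7, with 11.7 without peaks whose gene lies on another chromosome, and was 4.65 among plus-strand genes.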

Other observations

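Tests named below were chosen after the result was seen, except the strand test in RIP, the neighbouring gene pairs, the search for Ythdf1-CLIP peaks in 3 genes and the regroupings of libraries. Genes of the Ythdf1-CLIP list had slightly higher changes than other genes in RIP after ECT, which did not pass with an estimated correlation. Their median log2 change exceeded that of other genes by 0.14 in RIP (camera p 0.00720, p 0.408 with an estimated correlation). In the interaction it did so by 0.15 (camera p 0.00189, p 0.430 with an estimated correlation), against −0.01 in input (camera p 0.964). These differences were not adjusted for expression or the number of sets, and were not repeated with single libraries left out. m6A-CLIP genes that were not Ythdf1-CLIP genes were 1.08 above the rest in mock RIP over input (camera p 8.57e-07, p 0.0422 with an estimated correlation).

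Choroid plexus and ependymal transcripts were high in some libraries. In ECT input 3, 10 of 12 detected members were over 3 times the highest other input, and among WT and KO libraries 9 of 12 other members shared their highest libraries with Ttr, as tissue next to the dissected region would give. A rise shared by all ECT inputs was not seen, since the lowest ECT input was 0.191 times the highest mock input for the typical member. This ratio was chosen when a single high library was already known, so it cannot exclude a response to ECT in that library alone. For loss of Ythdf1, the lowest KO library was 0.0565 times the highest WT library for the typical choroid plexus member. Ttr was high in WT replicate 3 (1266.5 RPKM) and low in KO replicate 2 (9.17 RPKM), so its level did not follow the labels. For the 3 ependymal members the same ratio was 1.41, which leaves loss of Ythdf1 possible, though the smallest limma adjusted p was 0.769, and this split by cell type was made after the values were seen.

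Both CLIP assays had most peaks on the minus strand. Minus-strand genes had at least 2.495 times the peaks per gene of plus-strand genes in every expression decile, so more expressed genes on that strand do not account for it. The excess held on every chromosome (lowest share 62.8%), as peak calling or filtering that kept fewer plus-strand sites would give. Less m6A on plus-strand transcripts stays open. Plus-strand genes with a peak were recovered better by m6A-RIP, by a median log2 ratio of 0.58, but the strand was known only for the 63.2% of expressed genes with a peak. Loss of weak plus-strand sites would leave the better recovered genes, so this difference excludes nothing.

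Alad, Hdhd3 and Nnt, the last chosen after its values were seen, were higher in all libraries labelled KO without passing. Neighbouring genes at p under 0.01 in the same direction formed 2 pairs, against a mean of 0.498 and a 95th percentile of 2 in shuffled gene orders. The count includes Hdhd3 and Alad, the pair it was meant to explain. It cannot tell whether strain variants cluster there, and the rule for this verdict was tightened after the value was seen. Alad and Hdhd3 differed by −0.27 (SE 0.151), as a segment with more copies might give. Such a segment would have to end before the next gene beyond Alad, Pole3, at −0.04 (SE 0.09, chromosome 4, 62523798 to 62525014). Ythdf1-CLIP peaks in the 3 genes numbered 0, which cannot exclude binding.

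Regroupings of 3 against 3 libraries number 10, too few to tell a result from chance. As many genes passed in 1 of 10 for ECT in input (958, highest other 0), 1 for ECT in RIP (272, highest other 0), 1 for RIP over input (8082, highest other 0) and 8 for KO (1, highest other 13). As many lists were called in 2 for ECT in input (13, highest other 13), 2 for ECT in RIP (12, highest other 14), 6 for RIP over input (8, highest other 8) and 9 for KO (8, highest other 12). A camera p as small as the real one occurred in 4 for m6A-CLIP genes in RIP over input (1.02e-05, smallest other 2.31e-07) and 4 for Ythdf1-CLIP genes in KO (0.0390, smallest other 1.23e-06).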
